A study of Mus musculus with 12 samples.

How the data were processed

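Gene expression was measured in dendritic cells grown from mouse bone marrow that had been depleted of B and T cells and cultured for 5 days with GM-CSF at 10 ng/ml and IL-4 at 5 ng/ml. Cells were stimulated with LPS at 100 ng/ml for 0, 1, 6 or 24 h and collected by repeated pipetting, with no sort before RNA extraction named. Per the labels, 750 ng of labelled cRNA per sample was hybridised in Cy5 against a Cy3-labelled Universal mouse reference. That reference is a pool of mouse RNA that is the same on every array. Each of the 4 groups held 3 samples, given in the labels as biological replicates with letters A, B and C and called donors here.

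Per the file headers, the deposited scanner files came from Agilent Feature Extraction 10.7.3.1 with protocol GE2_107_Sep09, and hold for each of 45018 spots the median pixel intensity of spot and local background in each channel, in intensity units without normalization, together with quality marks and the scanner software's own processed signals, which are intensities after background subtraction, detrending and dye normalization. The deposited value table holds 1 log2 ratio of sample to reference per probe, normalised by the authors with limma per the labels; its version and the steps are not given in the sources used here. Its scale and direction were settled against the scanner files; the values derived here correlated with it across probes at r of at least 0.999 on every array, and all of its columns could be mapped to a sample.

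All comparisons were computed from the scanner files in R 4.3.3 with limma 3.58.1, reading the labels with jsonlite 2.0.0. The signals were corrected for background with normexp at an offset of 50, and log ratios were normalised within arrays by loess (span 0.3) with the 1639 control spots at weight 0. The plan had named mean spot signals, but the files hold medians only, and median signals were used. Applied as planned, with the local background of every spot, normexp failed on the 6 h array of donor B, where spot minus local background reached -50238 units. Local backgrounds marked as outliers were therefore replaced by the median of their array, and spots marked as feature outliers (92 to 161 per array) left out. Both were chosen after seeing the files, and the planned form is among the alternatives. With it, the correlation with the authors' values was 0.825 on that array and at least 0.995 on the others, and on 9 of the 12 arrays it was higher than with the form used.

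Of 41174 probes, 22951 were matched to a gene symbol through the RefSeq accession printed for the probe, in a reference table of accessions and symbols, and 18223 were not. No coordinates were used. Probes were kept if the scanner software called them well above background in the sample channel on all 3 arrays of at least 1 group, which left 21750 probes, 15104 of them with a symbol. For each gene the probe with the highest mean intensity was used, which gave 11095 genes; 3298 of these had more than 1 probe, and probes of 1 gene were called in opposite directions for 0 genes at 1 h, 5 at 6 h, 23 at 24 h, 2 at 6 h against 1 h and 2 at 24 h against 6 h. No spot was saturated, and 14 values were missing. Across arrays, 48.1 to 57.6% of probes were well above background in the sample channel and 58.6 to 68.7% in the reference channel, with median signals above background of 24 to 44 and 21 to 47. The number of arrays limits the precision.

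A linear model with 1 mean per group was fitted to all 12 arrays (8 residual degrees of freedom), with empirical Bayes moderation and two-sided tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called, and separately those that also changed by at least 2-fold. Comparisons were 1, 6 and 24 h against unstimulated cells, 6 h against 1 h and 24 h against 6 h, with a moderated F test for any difference between the groups. Slides were read from the headers and entered as a fixed block in an alternative (5 residual degrees of freedom), and differences within slides were taken beside it. Whether arrays of the same donor resembled each other was checked once on deviations from group means. Pairs of the same donor correlated across genes at a median r of 0.11 (-0.21 to 0.58 over 18 pairs), against -0.53 to 0.41 over 36 pairs of different donors. The 3 pairs were at 0.21, 0.54 and 0.55 between 1 h and 6 h and at 0.36, 0.58 and 0.21 between 1 h and 24 h, but at 0.06, -0.07 and -0.21 between unstimulated cells and 1 h. The pairing comes from the letters of the labels, which do not state that a letter is the same animal in every group. Donor as a block is an alternative, printed where it changes a call.

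Lists of genes, 23 of functions and 13 of cell type markers, with 763 distinct genes in all, of which 32 stand on more than 1 list, were tested against the other genes with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists of a kind within a comparison. Lists with fewer than 3 measured members were not tested. Camera with an estimated correlation and fry stand beside it. The PValue of fry asks whether the genes of a list move, on balance, one way, and its PValue.Mixed whether they change in either direction; neither compares a list with other genes. With the preset correlation 44 of 105 tests passed, 34 upward and 10 downward; with an estimated correlation only the immediate early, inflammatory cytokine, NF-kB pathway and antigen uptake lists at 1 h did. Counts adjusted over the list alone are given beside those adjusted over all genes tested.

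The genes named are the 8 highest and 8 lowest called genes of each comparison with unstimulated cells (5 and 5 between times) with a usual gene symbol that changed the same way in all 3 donors, 22 fixed marker genes whatever their result, and up to 3 risen and 3 fallen called members of each list with the largest change. Of the 22 fixed genes 18 were tested: Il12b, Cd40 and Mki67 had 0 named probes, and the 1 probe of Il10 was well above background on 2 of all 12 arrays. Mpo at 1 h was named after its value was seen. Some genes that the rule takes are not reported here. This rule, the lists, the comparisons, the tests and the first set of alternatives were fixed before the data were examined.

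Beside the choices above, 18 alternative settings and 12 fits that each left out 1 array were run. Planned were scanner processed signals, no background correction, Aquantile scaling, median centring, the Cy5 channel alone, the authors' values, no filter or a strict filter on dim probes (9432 genes), every probe as its own feature, the mean of a gene's probes, trend and robust moderation, only the groups compared, and blocks for slide and donor. The procedure was tested on simulated data with 50 genes at each of several sizes of change. Genes changed by 0.5 on the log2 scale were called in 16 to 34% of cases and those changed by 1 in 84 to 94%, and 3.16 to 5.85% of the calls were false. Only 200 of 11095 genes were changed there. Errors were independent between genes and arrays, without slide or donor effects, so these shares need not hold for the arrays themselves. Probes without a symbol were left out of the gene comparisons, and raw images were not used here.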

Results

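The series asked which genes respond to lipopolysaccharide (LPS) in mouse bone marrow-derived dendritic cells. LPS is a cell wall component of Gram-negative bacteria that is sensed through the receptor Tlr4, and the cells are antigen-presenting cells grown from marrow precursors with GM-CSF and IL-4. Messenger RNA was measured before stimulation and after 1, 6 and 24 h with LPS at 100 ng/ml. The only unstimulated cells were those of 0 h. In every comparison with them, added time in culture and handling cannot be told apart from LPS. Each of the 4 groups held 3 samples, which made 12 arrays. The labels give them as biological replicates with letters A, B and C, called donors here. Whether a letter stands for the same animal in every group is not stated in the labels. Every array compared 1 Cy5-labelled sample with a Cy3-labelled pooled mouse reference, so each value is a log2 ratio of the sample to that reference. Between 48.1 and 57.6% of the probes of an array were well above the local background in the sample channel, and the median sample signal above background was 24 to 44 intensity units. After filtering, 11095 genes were tested. Arrays of the same group correlated across genes at r = 0.946 to 0.984; genes are not independent replicates, so this describes the profiles only. The first principal component took 54.4% of the variance and the second 15%. The number of arrays, 3 per group, limits the precision of every value.

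The arrays lay on 4 slides. Slide 1 held the unstimulated arrays and the 1 h array of donor A, and slide 2 the 1 h and 24 h arrays of donor B. Slide 3 held the 1 h array of donor C with the 6 h arrays of donors A and B, and slide 4 the 6 h array of donor C with the 24 h arrays of donors A and C. No slide held unstimulated cells together with 6 h or 24 h cells. Each comparison is therefore given together with a fit that holds slide as a block, and with the difference taken within slides (chained through the 1 h arrays where needed). Both use arrays that also made the calls. Agreement in sign over called genes is therefore favoured by their selection and is no separate check. Log2 changes below are differences between group means with the limma standard error (SE), n = 3 arrays per group. The standard error of a gene is the same in every comparison, because the groups are of equal size and share 1 fit, save for 14 genes with a missing value. Where a probe was not well above background on any array of a group, the fold is a bound. It was taken from the sample channel alone after loess and between-array scaling, with the lowest signal called above background in place of the missing level, and remains open to dye bias because no dyes were swapped. Where that bound lay above the fold of the ratios, no size is given.

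The first comparison asked what had changed 1 h after LPS. The cells had already raised their inflammatory messengers. Nfkbiz, an atypical inhibitor of NF-kB proteins that promotes secondary response genes, was 95.5-fold higher than in unstimulated cells (log2 change 6.58, SE 0.38, adjusted p = 4.8e-07). The cytokine Il6 was 72.4-fold higher (6.18, SE 0.46), Il1a 36.8-fold (5.20, SE 0.19), Tnf 36.0-fold (5.17, SE 0.17) and Il1b 23.6-fold (4.56, SE 0.30). Ifnb1, which encodes interferon beta and was not above background on any unstimulated array, was at least 61.1-fold higher. Ccrl2, a chemerin-binding receptor, rose 40.3-fold and the chemokine Cxcl10 39.7-fold, the latter above background on 1 of 3 unstimulated arrays. The strongest falls were smaller. The neutrophil and monocyte calcium-binding protein S100a8 fell by 2.50 on the log2 scale (SE 0.56, adjusted p = 0.019), lactoferrin (Ltf) by 1.95 (SE 0.40), Ldhc by 1.75 (SE 0.44) and Fignl1 by 1.65 (SE 0.38). Gadd45g decreased by 1.62 (SE 0.20), the cytokine signalling inhibitor Socs1 by 1.58 (SE 0.17), Hic1 by 1.55 (SE 0.28) and Plac8 by 1.53 (SE 0.29).

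Gene groups fixed beforehand moved in step with these genes at 1 h. Where only the p with an estimated correlation is given, a list had passed with the preset correlation of 0.01. At 1, 6 and 24 h 19, 13 and 12 lists passed in that way, against up to 13, 15 and 14 in another split of the same arrays. Each other split mixes both groups unequally and so keeps part of the real difference, which makes those counts no measure of chance. The preset test alone is still weak evidence for a list, because few lists passed with an estimated correlation. Of 24 immediate early genes, 18 rose and none fell (19 adjusted over the list alone), with a median log2 change of 1.5 (1.46 with slide as a block; adjusted p = 1.4e-23, and adjusted p = 0.0041 with an estimated correlation). Egr1 rose by 3.81, the nuclear receptor Nr4a1 by 3.1 and the phosphatase Dusp2 by 3.03. Among 21 inflammatory cytokines 16 rose (17 adjusted over the list alone), with a median of 2.65 (2.44 with the block; adjusted p = 8.6e-24, and adjusted p = 0.043 with an estimated correlation). NF-kB pathway genes rose in 15 of 23 cases (19 adjusted over the list alone), including the feedback regulators Tnfaip3 (3.85) and Nfkbia (3.24). Their median was 0.75, or 0.79 with the block, and adjusted p = 0.049 with an estimated correlation. Chemokines rose in 12 of 19 cases (12 adjusted over the list alone), with Ccl4 at 3.36 and Ccl2 at 3.15, a median of 1.30 (1.22 with the block), and adjusted p = 0.057 with an estimated correlation. Of 22 genes of antigen uptake and scavenging, 4 rose (6 adjusted over the list alone), led by the lectin Clec4e (4.39) and the scavenger receptor Olr1 (2.97). The list had a median of 0.35 (0.30 with the block), and adjusted p = 0.043 with an estimated correlation.

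Few interferon-stimulated genes had changed at 1 h. Of 39, 7 rose (8 adjusted over the list alone), with Isg15 at 3.86, Rsad2 at 2.68 and Ifit1 at 2.22. Their median change was 0.01 (0.06 with the block, -0.08 with median centring and -0.07 for the Cy5 channel alone), their mean was 0.41, and the test of the list missed the threshold (adjusted p = 0.082), while fry found changes in either direction (6.3e-06). Dendritic cell maturation genes rose in 6 of 26 cases (9 adjusted over the list alone), with Marcksl1 at 1.53, Cd80 at 1.29 and Tnfsf4 at 1.26. The median change was 0.30 (0.36 with the block), and adjusted p = 0.216 with an estimated correlation. The signalling receptors and adaptors of the Toll-like receptor list rose in 5 of 25 cases (7 adjusted over the list alone), with the LPS co-receptor Cd14 at 3.35, Tlr2 at 2.15 and Tlr7 at 1.51. As a group they had a median of 0.16 (0.28 with the block), and adjusted p = 0.123 with an estimated correlation. Feedback inhibitors split, with 7 of 17 higher, such as Rgs1 (3.22), Socs3 (2.71) and Spry1 (2.37), and 2 lower, Socs1 and Dusp6 (-1.06). Adjusted over the list alone the counts were 10 and 2, with a median of 0.67 (0.49 with the block), and adjusted p = 0.123 with an estimated correlation. Apoptosis regulators rose in 7 of 22 cases (8 adjusted over the list alone), with Cflar at 2.08, Casp4 at 1.57 and Pmaip1 at 1.55. The group median was 0.20 (0.23 with the block), and adjusted p = 0.073 with an estimated correlation. IL-4 responsive genes rose in 4 of 22 cases, with Irf4 at 1.48, Mrc1 at 1.22 and Cish at 1.03, and fell in 1, Socs1. Adjusted over the list alone 9 rose and 1 fell, with a median of 0.40 (0.27 with the block), and adjusted p = 0.123 with an estimated correlation.

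Genes of cell division moved the other way at 1 h. Of 33 cell cycle genes, 7 fell and none rose (24 fell adjusted over the list alone), with Rrm2 at -1.05, Kif23 at -0.98 and Ccne2 at -0.91. The median was -0.88 (-0.76 with the block; adjusted p = 2.5e-12, and adjusted p = 0.232 with an estimated correlation). Markers of haematopoietic progenitors, which divide in such cultures, had a median of 0.02 (0.04 with the block, below 0 with median centring; adjusted p = 0.512), a mean of -0.10, and 1 of 7 lower, Cd34 (-0.95; 2 lower adjusted over the list alone). Neutrophil markers fell in 4 of 12 cases, S100a8, Ltf, Ctsg (-1.34) and Mpo (-0.94), while over the list alone 2 rose and 5 fell. Their median was -0.68 (-0.30 with the block; adjusted p = 0.029, and adjusted p = 0.150 with an estimated correlation). Lysosomal genes rose in 8 of 35 cases (24 adjusted over the list alone), with Gpnmb at 0.95 and Ctsk at 0.88, a median of 0.49 (0.51 with the block), and adjusted p = 0.123 with an estimated correlation.

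Other groups held few called genes at 1 h. Of 18 genes of nitric oxide and prostaglandin synthesis, 2 rose (5 adjusted over the list alone), cyclooxygenase-2 (Ptgs2), at least 6.35-fold, and the arginine transporter Slc7a2 (2.08). The members had a median of 0.32 (0.27 with the block), and adjusted p = 0.057 with an estimated correlation. Cytoskeleton and podosome genes rose in 3 of 32 cases (5 adjusted over the list alone), with Icam1 at 2.20. Their median was 0.19 (0.22 with the block), and adjusted p = 0.380 with an estimated correlation. None of the 33 genes of mitochondrial respiration and none of the 22 of cholesterol synthesis passed the test, alone or over their list. Their medians were -0.13 (-0.13 with the block) and -0.35 (-0.27 with the block), with adjusted p = 0.061 for each with the block, and adjusted p = 0.630 and adjusted p = 0.613 with an estimated correlation. The MHC class II list (2 of 16 higher, Lgmn 1.23 and Marchf1 0.85; adjusted p = 0.057) and the MHC class I list (3 of 15 higher, H2-D1 0.86 with adjusted p = 0.051 with donor as a block, H2-T23 0.53 and B2m 0.49; adjusted p = 0.228) did not pass; adjusted over the list alone 3 members of each rose, and 1 class I gene fell. Nor did glycolysis (2 of 23 higher, Slc2a6 1.07 and Hk3 0.65; adjusted p = 0.138), lipid handling and PPAR targets (1 of 21 lower, Angptl4 -1.15; adjusted p = 0.425), heat shock proteins (Dnajb4 1.13, Dnajb1 -0.87; adjusted p = 0.484; median -0.05 against a mean of 0.09) or the 45 cytosolic ribosomal proteins (none called; adjusted p = 0.137). Among the cell type markers, those of conventional dendritic cells rose in 2 of 12 cases (Irf4 and Id2, 0.97; adjusted p = 0.480 with an estimated correlation) and those of macrophages or monocytes in 2 of 13 (Cd14 and Mrc1; adjusted p = 0.150 with an estimated correlation). Their medians were 0.26 and 0.49 (0.21 and 0.39 with the block, with adjusted p = 0.071 and 0.027; 0.062 and 0.061 with donor as a block), and adjusted over the list alone 4 and 6 rose and 1 of each fell. With the block the medians were 0.32 for class II, which passed there (adjusted p = 0.0064), 0.31 for class I, 0.33 for glycolysis (adjusted p = 0.017), 0.20 for lipid handling, -0.03 for heat shock proteins and 0.06 for ribosomal proteins. With an estimated correlation, fitted without the block, class II and glycolysis had adjusted p = 0.453 and 0.630. Adjusted over the list alone 3 heat shock genes rose and 3 fell, and the counts for glycolysis, lipid handling and ribosomal proteins were the same. The medians of glycolysis, lipid handling and ribosomal proteins turned negative with median centring.

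Across all genes, 827 of 11095 differed at 1 h in the limma test (7.45%), 451 higher and 376 lower, and 278 of them by at least 2-fold, 214 higher and 64 lower. Of the fixed marker genes not yet named, Fos rose by 1.29 (SE 0.21) and Ccl5 by 1.17 (SE 0.31), while the inducible nitric oxide synthase Nos2 (0.96, adjusted p = 0.053, or 0.017 with donor as a block; above background on 1 of 3 unstimulated arrays), Tlr4 (0.79, adjusted p = 0.044 with donor as a block), Ccr7 (0.47), Pparg (0.33), Cd86 (0.30), H2-Ab1 (0.20) and Ciita (-0.38) did not pass. With slide as a block, which at 1 h rests on slide 1 alone (1 LPS array against 3), 225 genes passed, 170 higher and 55 lower, and 217 of the 827 kept their call and direction. Every one of the 827 had the same sign there, but the block's estimate uses arrays that also made the calls. The rises of Nfkbiz (6.40), Il6 (6.04), Ifnb1, Ccrl2 (5.12), Cxcl10 (5.06), Il1a (5.03), Tnf (5.15) and Il1b (4.33) kept their call there, as did the falls of S100a8 (-1.99), Gadd45g (-1.53), Socs1 (-1.44) and Hic1 (-1.40). Of the 75 called genes that the naming rule takes at 1 h, 42 kept their call with the block. Among the others were the falls of Ltf (-1.20), Ldhc (-1.59), Fignl1 (-1.61) and Plac8 (-1.13), and the rises of Ptgs2, Ccl5 (1.17), Rsad2 and Ifit1. The share of higher genes was 54.5%, but 79.6% with median centring in place of loess (179 higher, 46 lower) and 38.0% with the Cy5 channel alone (287 higher, 469 lower). With normexp on all spots as deposited 243 genes passed. Among genes changed by at least 2-fold, 77.0% were higher, or 65.0% with the Cy5 channel alone and 60.8% with the scanner software's processed signals. Without the unstimulated array of donor A 338 genes passed, without that of donor B 356, and without the 1 h arrays of donors A or B 528 and 399.

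**Figure D1:**
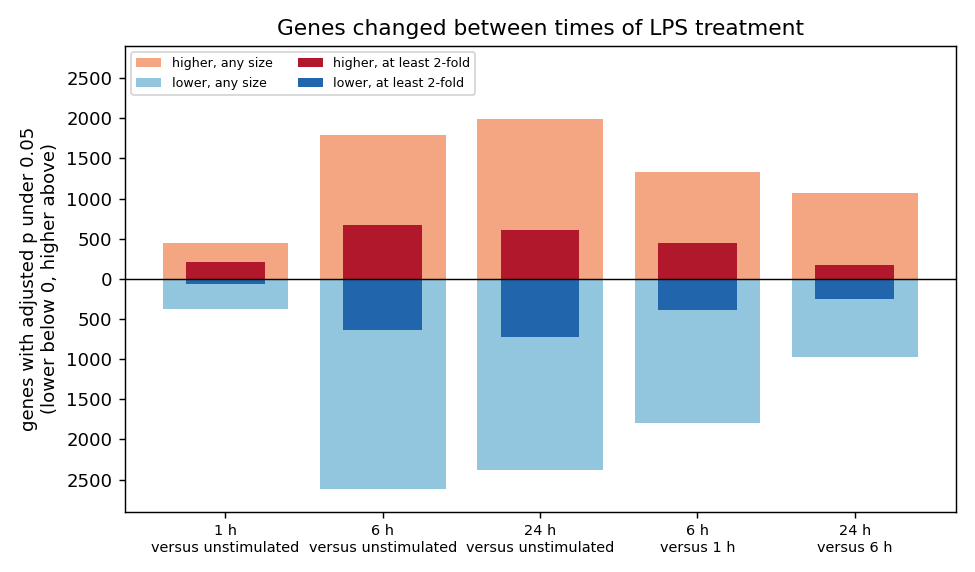
Bars give the number of genes that were higher or lower in each of the 5 comparisons, at adjusted p under 0.05 (any size) and with a change of at least 2-fold. The counts rise from 827 genes at 1 h to 4397 at 6 h and 4372 at 24 h; 2042 genes differed between 24 h and 6 h.

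The second comparison asked what had changed by 6 h. Genes of the antiviral interferon response made up most of the strongest rises. Rsad2, which encodes the antiviral enzyme viperin, was 327-fold higher than in unstimulated cells (log2 change 8.35, SE 0.44, adjusted p = 5.9e-08). Cxcl10 was 188-fold higher (7.55, SE 0.49), the ubiquitin-like protein Isg15 77.2-fold (6.27, SE 0.22), Oasl1 74.7-fold (6.22, SE 0.24), the nucleotide kinase Cmpk2 66.5-fold (6.05, SE 0.32) and Ifit1 54.3-fold (5.76, SE 0.45). Il6 stood at 91.8-fold (6.52, SE 0.46), and neurotensin (Nts), a neuropeptide, at 59.4-fold (5.89, SE 0.41). The strongest falls were those of Cyp2s1, a cytochrome P450 (-3.57, SE 0.63, adjusted p = 0.00071), S100a8 (-3.52, SE 0.56), the lipase Daglb (-3.37, SE 0.22), and the neutrophil chemokine receptor Cxcr2 (-3.17, SE 0.61; above background on 2 of 3 arrays at 6 h). They were followed by the kinase Aatk (-3.16, SE 0.30; above background on 1 of 3 arrays at 6 h), Asb4 (-2.97, SE 0.31), Tiam2 (-2.95, SE 0.40) and Pald1 (-2.89, SE 0.15; 2 of 3 arrays).

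Of 39 interferon-stimulated genes, 38 had risen at 6 h (38 adjusted over the list alone), with a median of 3.44 (3.59 with slide as a block, 3.71 within slides; adjusted p = 2.1e-38). The 39th, Ifi44, named after its value was seen, was not called. With an estimated correlation this list, the NF-kB list, the cytokine list and the MHC class I list all had adjusted p = 0.079. Inflammatory cytokines rose in 20 of 21 cases, with Il1a at 5.13 and Il1b at 4.51 and a median of 2.41 (2.71 with the block, 2.84 within slides). NF-kB pathway genes rose in 22 of 23, with Nfkbiz at 4.11, Tnfaip2 at 2.60 and Tnfaip3 at 2.34 and a median of 1.18 (1.32 with the block, 1.34 within slides). For cytokines and NF-kB genes the counts were the same adjusted over the list alone. Chemokines rose in 13 of 19 cases (14 adjusted over the list alone), with Cxcl3 at 4.60 and Ccl5 at 4.42, a median of 1.87 (1.77 with the block, 2.24 within slides), and adjusted p = 0.095 with an estimated correlation. Of the 15 genes of MHC class I presentation, 11 rose (11 adjusted over the list alone), led by the peptide transporter Tap1 (2.17) with Tapbpl (1.93) and Tapbp (1.76). The list had a median of 1.10 (1.17 with the block, 1.09 within slides). The MHC class II list went both ways at 6 h and did not pass (adjusted p = 0.299). Ctss (0.69), H2-Oa (0.62) and H2-Aa (0.59) were higher and H2-DMa (-0.74) and Ifi30 (-0.47) lower. Adjusted over the list alone 3 were higher and 1 lower. The direction of H2-Aa turned with processed scanner signals and with normexp on all spots, and that of H2-Oa with the latter.

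Maturation genes of dendritic cells rose in 14 of 26 cases (15 adjusted over the list alone), with Marcksl1 at 3.12, Il15ra at 2.60 and the costimulatory ligand Cd80 at 2.22. The median change was 0.72 (0.87 with the block, 0.96 within slides), and adjusted p = 0.117 with an estimated correlation. Toll-like receptors and adaptors rose in 12 of 25 cases, with Cd14 at 2.84, Tlr7 at 2.25 and Tlr1 at 2.16. Adjusted over the list alone 14 rose and 1 fell. As a group they had a median of 0.41 (0.62 with the block, 0.71 within slides), and adjusted p = 0.097 with an estimated correlation. Apoptosis regulators rose in 11 of 22 cases and fell in 2 (the same counts adjusted over the list alone), with Casp4 at 3.59, Cflar at 2.23 and Traf1 at 1.95 against Bmf at -0.73 and Casp9 at -0.64. The group median was 0.32 (0.35 with the block, 0.45 within slides), and adjusted p = 0.079 with an estimated correlation. Of 24 immediate early genes, 10 were higher at 6 h and 3 lower (the same counts adjusted over the list alone). Gadd45b stood at 2.66, Plk2 at 2.31 and Dusp2 at 1.72, and Myc at -0.66, Jun at -0.57 and Fos was lower (adjusted p = 0.030; not well above background on any 6 h array). The members had a median of 0.34 (0.17 with the block, 0.41 within slides), and adjusted p = 0.328 with an estimated correlation. With all marked spots left out that median turned negative and the list lost its call. Lysosomal genes rose in 15 of 35 cases and fell in 2 (17 and 2 adjusted over the list alone), with the cathepsin Ctsl at 1.59 and Npc2 at 1.30 against Gusb at -1.14. Their median was 0.38 (0.40 with the block, 0.56 within slides), and adjusted p = 0.432 with an estimated correlation.

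Lists of the cell cycle, of cholesterol synthesis and of mitochondrial respiration shifted downward at 6 h, with the preset correlation alone. Of 33 cell cycle genes 31 fell (31 adjusted over the list alone), with Cdc20 at -2.79, Birc5 (survivin) at -2.77 and Rrm2 at -2.47. Their median was -1.59 (-1.65 with the block, -2.16 within slides; adjusted p = 1.2e-09, and adjusted p = 0.342 with an estimated correlation). Beside it stood a progenitor marker median of -0.13 (-0.10 with the block) with 1 of 7 lower, Kit (-0.48). Cholesterol synthesis genes fell in 11 of 22 cases (12 adjusted over the list alone), with Dhcr7 at -2.70 and Sqle at -1.68, a median of -0.73 (-0.89 with the block, -1.18 within slides), and adjusted p = 0.478 with an estimated correlation. Lipid handling and PPAR targets fell in 8 of 21 cases and rose in 4 (8 and 5 adjusted over the list alone), with the fatty acid synthase Fasn at -2.72, Scd2 at -2.53 and Angptl4 at -1.50 against Nr1h3 at 1.42, Fabp4 at 0.67 and Nr1h2 at 0.58 (median -0.22, -0.17 with the block; adjusted p = 0.299). Mitochondrial respiration genes fell in 10 of 33 cases (10 adjusted over the list alone), with Idh3a at -1.71, Ppargc1b at -1.54 and Fh1 at -1.30, a median of -0.27 (-0.31 with the block, -0.45 within slides), and adjusted p = 0.637 with an estimated correlation. Neutrophil markers fell in 8 of 12 cases, such as S100a8, Cxcr2 and Ltf (-2.64), and rose in 2, lipocalin-2 (Lcn2, 1.91) and Csf3r (adjusted p = 0.0013). The list had a median of -1.10 (-0.76 with the block, -0.71 within slides; adjusted p = 0.419 against other genes, and 0.00043 in fry for a fall on balance).

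Several groups split at 6 h and did not pass as lists. In nitric oxide and prostaglandin synthesis 7 of 18 rose and 4 fell (7 and 5 adjusted over the list alone; adjusted p = 0.173): Ptgs2 was at least 18.1-fold higher, Nos2 rose by 3.20 and Slc7a2 by 2.67, while Ptgs1 (-2.55), Tbxas1 (-1.02) and Alox5 (-0.65) fell. The median of that list was 0.01 (-0.02 with the scanner software's processed signals). Feedback inhibitors rose in 6 of 17 cases (Rgs1 2.43, Socs3 2.33, Peli1 2.28) and fell in 7 (Sigirr -1.91, Dusp6 -1.41, Pdlim2 -1.11; adjusted p = 0.669). IL-4 responsive genes rose in 4 of 22 cases (Irf4 1.38, Pdcd1lg2 0.91, Cish 0.61) and fell in 4 (Cdh1 -2.00, Clec10a -1.24, Tgm2 -0.97; adjusted p = 0.60; median 0.04, mean -0.02). Uptake and scavenging genes rose in 7 of 22 cases (Clec4e 4.78, Marco 4.29, Olr1 2.33) and fell in 2 (Scarb1 -1.44, Stab1 -0.61; adjusted p = 0.055; median 0.08, or -0.05 with the block). Cytoskeleton genes rose in 9 of 32 cases (Icam1 1.71, Itga5 1.31, the actin bundler Fscn1 1.31) and fell in 4 (Stmn1 -1.96, Myo1e -1.57, Tubb6 -1.17; adjusted p = 0.091). In glycolysis 3 of 23 rose (Slc2a6 1.26, Hk3 1.05, Hif1a 0.93) and 5 fell, such as Slc16a1 (-1.38), with adjusted p = 0.847; its median of -0.09 and fry pointed down and the camera test up. Heat shock proteins rose in 4 of 17 cases, led by Hspa1a (3.63), and fell in 5, such as Hspd1 (-1.18; adjusted p = 0.713; median -0.26, mean 0.06), and none of the 45 ribosomal proteins was called (adjusted p = 0.055, or 0.045 with donor as a block; median 0.15). Adjusted over the list alone 7 uptake genes rose and 3 fell, 4 heat shock genes rose and 7 fell, and the counts for feedback, IL-4, cytoskeleton, glycolysis and ribosomal genes were the same. With the block the medians were 0.11 for nitric oxide and prostaglandin synthesis, 0.10 for feedback inhibitors, 0.22 for IL-4 responsive genes, 0.26 for the cytoskeleton and 0.40 for MHC class II, and 0.27 for ribosomal proteins, which passed there (adjusted p = 0.013, but 0.806 with an estimated correlation and no block). Glycolysis had a median of -0.005 with the block, and that of heat shock proteins changed sign to 0.002.

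In all, 4397 genes differed at 6 h (39.6% of those tested), 1785 higher and 2612 lower, and 1314 by at least 2-fold, 675 higher and 639 lower. Of the fixed genes not yet named, Tnf was 4.44 above unstimulated (SE 0.17), Cd86 1.92 (SE 0.17), Ccr7 0.78 (adjusted p = 0.029), Ifnb1 higher (adjusted p = 0.00048) and Pparg 1.21 lower (-1.21, SE 0.14), while Egr1 (-0.57, adjusted p = 0.092), Tlr4 (-0.51), Ciita (0.47, adjusted p = 0.0495 with donor as a block) and H2-Ab1 (0.04) did not pass. With slide as a block 1949 genes passed, 948 higher and 1001 lower, and 1904 of the 4397 kept call and direction. Within slides 3 and 1, 4375 of 4396 had the same sign. The highest and lowest genes kept their calls there, with Rsad2 at 8.21 (8.78 within slides), Cxcl10 7.52, Il6 6.89, Isg15 6.17, Cyp2s1 -3.36 and S100a8 -3.60. The naming rule takes 142 called genes at 6 h, of which 106 kept their call with the block. Ifnb1, Myc, Jun and Fos were among those that did not. The direction of Fos turned within slides and with normexp on all spots as deposited, and that of Ccr7 turned with the latter. The share of higher genes, 40.6%, was 67.3% with median centring (1363 higher, 661 lower), and 51.4 against 64.6% among genes changed by at least 2-fold. In all 2024 genes passed with median centring and 2435 with normexp on all spots.

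**Figure D2:**
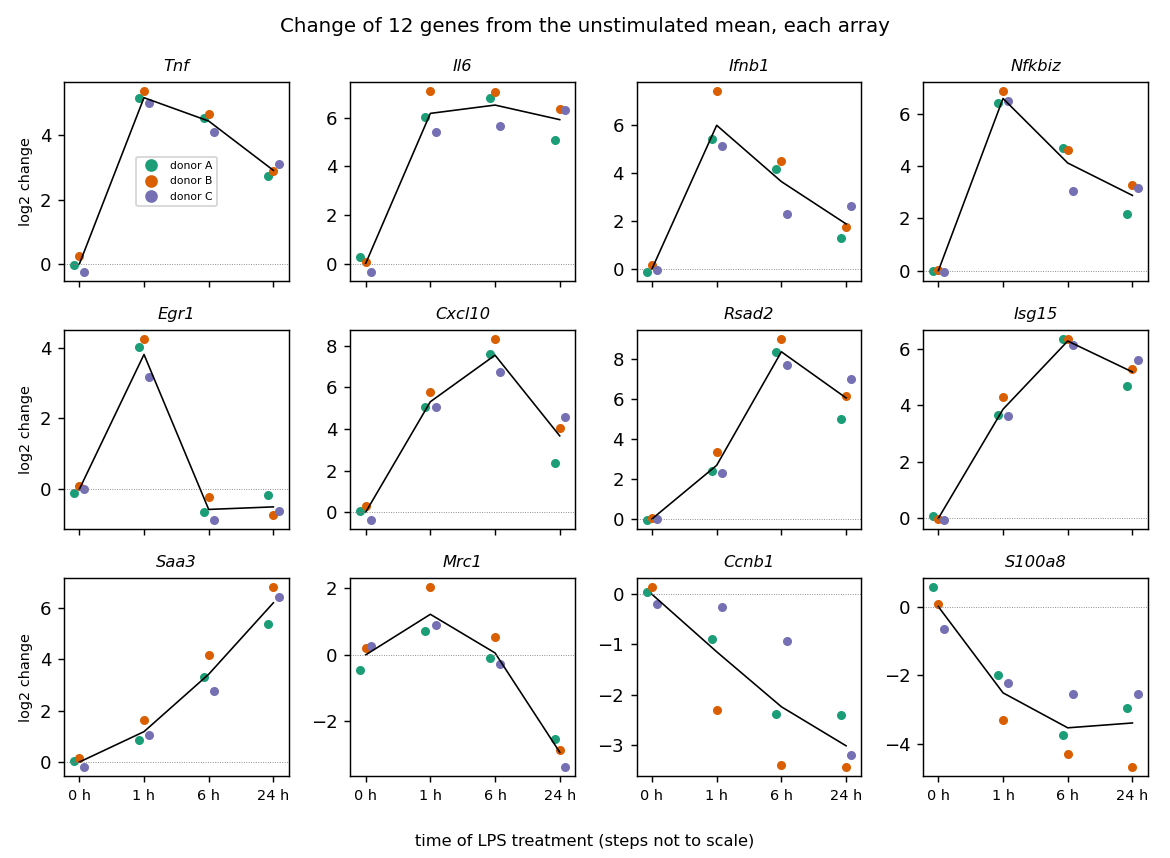
Each panel gives the log2 change of 1 gene from the unstimulated mean on every array against hours after LPS, with points by donor and a line through the group means. Rsad2 climbs to a mean of 8.35 at 6 h and stands at 6.05 at 24 h, while Egr1 is at 3.81 at 1 h and -0.57 at 6 h.

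The third comparison asked what had changed by 24 h. The strongest rises were no longer mainly those of interferon-stimulated genes. The acute phase protein Saa3 was 74.0-fold higher than in unstimulated cells (log2 change 6.21, SE 0.38, adjusted p = 2.7e-07), the scavenger receptor Marco 38.2-fold (5.26, SE 0.21), and the metalloproteinase inhibitor Timp1 40.1-fold (5.33, SE 0.39). Rsad2 (66.1-fold, 6.05, SE 0.44), Il6 (60.6-fold, 5.92, SE 0.46), Oasl1 (50.2-fold, 5.65, SE 0.24), Cxcl3 (42.3-fold, 5.40, SE 0.59) and Ccl5 (38.0-fold, 5.25, SE 0.31) were also among the highest. The lowest were the Fc receptor-like gene Fcrls (-3.75, SE 0.22), Birc5 (-3.75, SE 0.61, adjusted p = 0.00044), and the lectin Clec4b1 (-3.68, SE 0.38). Next came the integrin Itgb7 (-3.62, SE 0.22), the microtubule regulator Stmn1 (-3.48, SE 0.44), S100a8 (-3.38, SE 0.56), the histone H2ac15 (-3.21, SE 0.47) and the lamin Lmnb1 (-3.19, SE 0.27).

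Interferon-stimulated genes were still higher in 36 of 39 cases at 24 h (37 adjusted over the list alone), with Isg15 at 5.18 and a median of 2.08 (2.28 with slide as a block, 2.08 within slides). This list and those of inflammatory cytokines, NF-kB, chemokine, maturation, MHC class I, immediate early and apoptosis genes passed with the preset correlation, and all had adjusted p = 0.170 with an estimated correlation. Inflammatory cytokines rose in 18 of 21 cases (20 adjusted over the list alone), with Il1b at 4.66 and Il1a at 4.64 and a median of 2.06 (2.34 with the block, 2.26 within slides). NF-kB pathway genes rose in 19 of 23 cases and fell in 1, the NF-kB inhibitor Tnip3 (-0.86), with Nfkbiz at 2.88, Tnfaip2 at 2.41 and Nfkbia at 2.23 and a median of 1.00 (1.19 with the block, 1.09 within slides). Chemokines rose in 9 of 19 cases (12 higher and 1 lower adjusted over the list alone), with Cxcl10 at 3.67 and a median of 1.66 (1.48 with the block, 0.89 within slides). Maturation genes rose in 17 of 26 cases, with Cd200 at 2.46, Marcksl1 at 2.25 and the costimulatory ligand Cd86 at 1.95, and fell in 1, Icosl (-0.40). When adjusted over the list alone 19 rose and 1 fell, and the median was 0.96 (1.09 with the block, 0.95 within slides). MHC class I genes rose in 11 of 15 cases, with H2-D1 at 2.17, Tap1 at 1.67 and Tapbpl at 1.67, and fell in 1, calreticulin (Calr, -0.45), with a median of 0.79 (1.07 with the block, 1.14 within slides). MHC class II genes did not pass as a list (adjusted p = 0.846), with H2-Oa (0.78) and Rfxank (0.50) higher and H2-DMa (-1.12) lower of 16.

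Immediate early genes rose in 12 of 24 cases and fell in 3 at 24 h, with Gadd45b at 2.50, Nr4a2 at 2.38 and Dusp1 at 2.29 against Myc at -1.91, Egr2 at -0.87 and Jun at -0.82 (median 0.58, 0.54 with the block). Apoptosis regulators rose in 11 of 22 cases and fell in 2, with Casp4 at 2.97, Traf1 at 2.02 and the death receptor Fas at 1.73 against Bcl2 at -1.23 and Bcl2l11 at -0.81 (median 0.46, 0.52 with the block). For these lists, and for the NF-kB and MHC class I lists, counts were the same adjusted over the list alone. Toll-like receptors and adaptors rose in 11 of 25 cases, with Cd14 at 4.54, Tlr1 at 1.73 and Ly96, the LPS-binding partner of Tlr4, at 1.54. The median change was 0.23 (0.40 with the block), and adjusted p = 0.186 with an estimated correlation. In nitric oxide and prostaglandin synthesis 10 of 18 rose and 4 fell: Ptgs2 was at least 21.2-fold higher, the prostaglandin E synthase Ptges rose by 3.64 and Nos2 by 3.00, while Ptgs1 (-1.97), Tbxas1 (-1.15) and Alox15 (-1.03) fell. That list missed the threshold (adjusted p = 0.056; median 0.67), which it passed with slide as a block (median 0.86, adjusted p = 0.021). Lysosomal genes, with 12 of 35 higher, such as Npc2 (1.83), Gpnmb (1.55) and Ctsz (1.48), and 5 lower, such as Gusb (-1.27) and Ctsc (-1.20), also passed with the block (median 0.35, adjusted p = 0.042, against 0.26 and adjusted p = 0.052). With an estimated correlation, fitted without the block, these lists had adjusted p = 0.170 and 0.700.

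Cell cycle genes were lower at 24 h in 31 of 33 cases (31 adjusted over the list alone), with Birc5, Ccnb2 (-3.11) and Cdc20 (-3.09). Their median was -1.90 (-1.86 with the block, -1.21 within slides; adjusted p = 9.7e-15, and adjusted p = 0.206 with an estimated correlation). Beside it stood a progenitor marker median of -0.04 (0.05 with the block) with Cd93 (-1.12) and Kit (-0.42) lower and Ly6a higher (adjusted p = 0.0029). Mitochondrial respiration genes fell in 19 of 33 cases (22 adjusted over the list alone), with Idh3a at -1.72, Fh1 at -1.59 and Ppargc1b at -1.39, a median of -0.52 (-0.58 with the block, -0.38 within slides), and adjusted p = 0.335 with an estimated correlation. Cholesterol synthesis genes fell in 13 of 22 cases (14 adjusted over the list alone), with Dhcr7 at -1.85 and Cyp51 at -1.49, a median of -0.83 (-0.92 with the block, -0.49 within slides), and adjusted p = 0.547 with an estimated correlation. Lipid handling and PPAR targets fell in 9 of 21 cases, such as Fasn (-2.56), Scd1 (-1.53) and Pltp (-1.25), and rose in 3, Nr1h3 (0.85), Fabp4 (0.78) and Nr1h2 (0.67), without passing as a list (median -0.61, -0.59 with the block; adjusted p = 0.052, or 0.046 with donor as a block and 0.239 with an estimated correlation). Neutrophil markers fell in 9 of 12 cases, such as S100a8, Ltf (-2.61) and Cxcr2 (-2.60), with Lcn2 at 3.05 and Csf3r at least 1.44-fold higher. Macrophage or monocyte markers fell in 7 of 13, such as the mannose receptor Mrc1 (-2.92) and Ccr2 (-1.95), with Cd14 and Adgre1 (0.94) higher. Their medians were -1.0 and -0.68 (-1.16 and -0.72 with the block), each with adjusted p = 0.093 against other genes (8 macrophage markers lower adjusted over the list alone, other counts the same) and 0.00032 in fry for a fall on balance.

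Other lists split at 24 h and did not pass. IL-4 responsive genes rose in 8 of 22 cases (Il4ra 1.5, Pdcd1lg2 1.15, Irf4 1.07) and fell in 6 (Mrc1, Clec10a -2.64, Cdh1 -1.98; adjusted p = 0.850; median 0.06, mean -0.18). Uptake and scavenging genes rose in 8 of 22 cases (Marco, Clec4e 4.91, Olr1 2.87) and fell in 7 (Mrc1, Mgl2 -1.53, Clec4a2 -1.33; adjusted p = 0.821), with a median of -0.11 although their mean, 0.39, and their tests pointed up. Feedback inhibitors rose in 7 of 17 cases (Socs3 2.61, Dusp4 2.17, Rgs1 2.11) and fell in 5 (Rgs2 -1.71, Trib1 -1.32, Dusp6 -1.23; adjusted p = 0.345; median 0.40, or -0.03 within slides). Cytoskeleton genes rose in 11 of 32 cases (Itga5 1.46, Fscn1 1.15, Icam1 1.04) and fell in 8 (Stmn1, Gsn -1.18, Myo1e -1.09; adjusted p = 0.709), with a median of -0.03 while the tests pointed up. In glycolysis Pfkfb3 (1.01), Hk3 (0.91) and Hif1a (0.86) were among 5 of 23 higher genes and Slc16a1 (-1.82), Pfkfb4 (-1.02) and Gpi1 (-0.72) the 3 lower ones (adjusted p = 0.821). Heat shock proteins rose in 4 of 17 cases (Hspa1a 5.10, Dnajb4 1.29, Hspb1 1.24) and fell in 4, among them Hspd1 (-1.08), Dnajb1 (-0.58) and Hspe1 (-0.44), with adjusted p = 0.822 and a median of -0.11 against a mean of 0.35. Cytosolic ribosomal proteins fell in 5 of 45 cases (1 adjusted over the list alone), such as Rpl14 (-0.96), Rps19 (-0.56) and Rps2 (-0.50), with a median of -0.18, or 0.02 within slides (adjusted p = 0.118, but 0.00019 without slide 2; 0.921 with an estimated correlation). Adjusted over the list alone 10 IL-4 responsive genes rose and 7 fell, 8 uptake genes rose and 8 fell, and 11 cytoskeleton genes rose and 9 fell, with the other counts the same save that of the ribosomal proteins. With the block the medians were 0.13 for IL-4 responsive genes, -0.44 for uptake, 0.15 for feedback inhibitors, 0.08 for the cytoskeleton, 0.01 for glycolysis, 0.05 for heat shock proteins and -0.09 for ribosomal proteins. The medians of the IL-4 and MHC class II lists turned negative with median centring.

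In all, 4372 genes differed at 24 h (39.4%), 1992 higher and 2380 lower, and 1332 by at least 2-fold, 605 higher and 727 lower. Of the fixed genes not yet named, Tnf was 7.54-fold higher (2.91, SE 0.17), Ccr7, the receptor that guides dendritic cells to lymph nodes, 2.38-fold higher (1.25, SE 0.26), Ifnb1 at least 3.46-fold higher (adjusted p = 0.027) and Pparg lower (-1.09, SE 0.14). Egr1 (-0.49), Ciita (-0.32), H2-Ab1 (0.24), Fos (-0.18) and Tlr4 (-0.05) did not pass. With slide as a block 1762 genes passed, 849 higher and 913 lower, and 1710 of the 4372 kept call and direction. Within slides 2 and 1, 4307 of 4372 had the same sign. Saa3 (6.31 with the block, 6.03 within slides), Marco (4.76 and 4.73), Cxcl3 (4.38 and 3.55), Birc5 (-4.02 and -2.46) and the other highest and lowest genes kept their calls. Of 150 called genes that the naming rule takes at 24 h, 108 kept their call. Among those that did not were Ifnb1, whose direction turned within slides, Egr2, Jun, Tnip3 and Icosl. The share of higher genes, 45.6%, was 35.7% with median centring (833 higher, 1502 lower), and 45.4 against 32.2% among genes changed by at least 2-fold. Median centring moved the median of all genes to -0.12 at 1 h, 0.05 at 6 h and -0.11 at 24 h, against 0.02, -0.04 and 0.02.

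**Figure D3:**
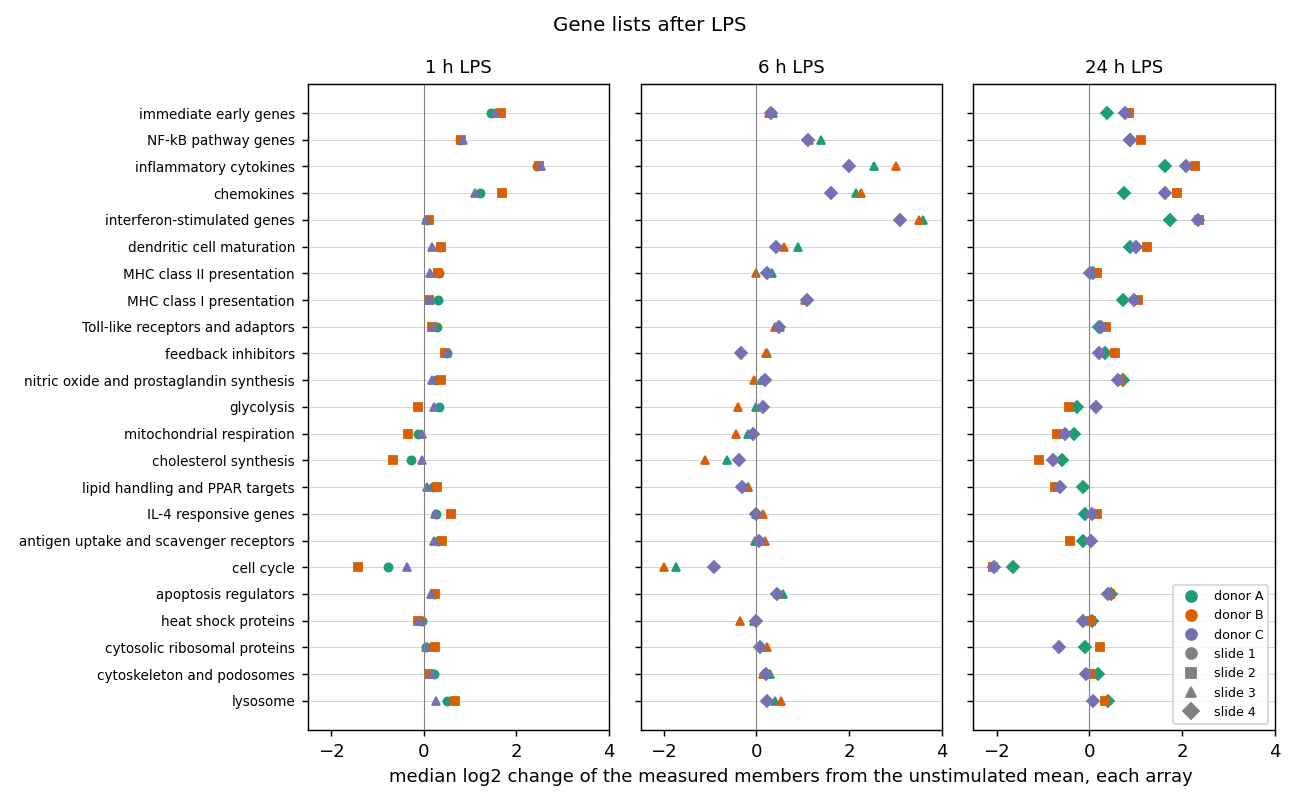
Each line is 1 of the 23 function lists and each point the median log2 change of its measured members on 1 array from the unstimulated mean, with colours for donors and shapes for slides, in panels for 1, 6 and 24 h. Interferon-stimulated genes lie far to the right at 6 h, with a median of 3.44 for the group, and cell cycle genes to the left at every time.

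The direct comparison of 6 h with 1 h asked which changes built up or faded over those hours. Interferon-stimulated genes took the top places, with Cmpk2 55.4-fold higher at 6 h (5.79, SE 0.32, adjusted p = 1.3e-07), Rsad2 51.0-fold (5.67, SE 0.44), Oasl2 31.3-fold (4.97, SE 0.17), Ifit2 29.8-fold (4.90, SE 0.35; above background on 1 of 3 arrays at 1 h) and Ifi209 27.4-fold (4.78, SE 0.29). The immediate early gene Egr1 fell by 4.37 on the log2 scale (SE 0.25, adjusted p = 1.4e-07), Errfi1, a feedback inhibitor of growth factor receptors, by 3.73 (SE 0.17), Daglb by 3.24 (SE 0.22), Tiam2 by 3.21 (SE 0.40) and the stress cytokine Gdf15 by 3.18 (SE 0.41). Of the fixed genes, Ccl5 (3.24), Isg15 (2.41), Cxcl10 (2.24), Nos2 (2.24), Cd86 (1.63) and Ciita (0.85) were higher at 6 h than at 1 h, and Ifnb1 (-2.35), Pparg (-1.54), Tlr4 (-1.30), Tnf (-0.73) and Fos (adjusted p = 3.1e-05) lower. Il6 (0.34), Il1b (-0.05), Ptgs2 (1.47, adjusted p = 0.077), Ccr7 (0.32), H2-Ab1 (-0.16) and Cd14 (-0.51) did not pass. The test called 3128 genes, 1331 higher and 1797 lower, and 831 by at least 2-fold, 445 higher and 386 lower. With slide as a block 2341 of them kept call and direction, and all 3128 had the same sign on slide 3 (2 arrays against 1), whose arrays the calls also used. Cmpk2 (5.87), Rsad2 (5.81), Egr1 (-4.14, and -3.60 on slide 3) and Errfi1 (-3.95) kept their calls, but Tnf, Ifnb1 and Ciita did not. Without the 6 h array of donor A 2083 genes passed. Median centring gave 1449 genes, 83.0% of them higher in place of 42.6%, and moved the median of all genes from -0.09 to 0.13. Among genes changed by at least 2-fold the share was 80.7 in place of 53.5%.

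The comparison of 24 h with 6 h asked what changed late. Saa3 rose a further 6.90-fold (2.79, SE 0.38, adjusted p = 0.00042), and Cyp1b1, a cytochrome P450, rose by 2.70 (SE 0.33), Enpp2, which encodes autotaxin, by 2.68 (SE 0.20), Vnn3 by 2.50 (SE 0.46) and Plac8 by 2.46 (SE 0.29). Cxcl10 fell by 3.88 (SE 0.49, adjusted p = 0.00027), the cholesterol 25-hydroxylase Ch25h by 3.58 (SE 0.62), Fcrls by 3.31 (SE 0.22), Lhx2 by 3.1 (SE 0.39) and Cmpk2 by 3.00 (SE 0.32). Of the other fixed genes Cd14 rose (1.70, SE 0.30), and Tnf (-1.53, SE 0.17) and Isg15 (-1.09, SE 0.22) fell. Ifnb1 (-1.76, adjusted p = 0.063) and Ciita (-0.79) did not pass, but both were called with donor as a block (adjusted p = 0.037 and adjusted p = 0.0092). Ccl5 (0.83, adjusted p = 0.080), Il6 (-0.60), Il1b (0.15), Nos2 (-0.20), Ptgs2 (0.22), Egr1 (0.07) and Fos did not pass. Nor did Tlr4 (0.46), Ccr7 (0.47), Cd86 (0.03), H2-Ab1 (0.20) and Pparg (0.13). The test called 2042 genes, 1070 higher and 972 lower, and 425 by at least 2-fold, 173 higher and 252 lower. With slide as a block 825 of them kept call and direction, among them every gene named here as called, with Saa3 at 2.94 and Cxcl10 at -3.66. All 2042 had the same sign on slide 4 (2 arrays against 1), whose arrays the calls also used. Without the 6 h array of donor A 1080 genes passed, without that of donor B 1290, and without the 24 h array of donor C 1270. Median centring gave 928 genes, 10.5% of them higher in place of 52.4%, and moved the median of all genes from 0.04 to -0.18. Among genes changed by at least 2-fold the share was 11 in place of 40.7%.

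Over the whole time course, 5739 genes (51.7%) differed between the 4 groups in limma's moderated F test. Changes were largest at 1 h for 328 higher and 242 lower genes, at 6 h for 1106 higher and 1471 lower, and at 24 h for 1123 higher and 1469 lower. In the single comparisons, 269 genes were called higher and 230 lower at all 3 times, 904 and 1488 at 6 and 24 h but not at 1 h, 558 and 853 at 6 h alone, 784 and 638 at 24 h alone, and 93 and 81 at 1 h alone. A call at one time and not at another is no test of the difference between them. Because all times were set against the same unstimulated arrays, their changes share error. Across genes, the changes at 1 h and 6 h correlated at r = 0.594, those at 1 h and 24 h at 0.571, and those at 6 h and 24 h at 0.818, where simulated data without any effect gave 0.498, 0.497 and 0.498. Called at both 6 h and 24 h were 1173 higher and 1718 lower genes, where independent lists would share 320 and 560 and the simulation 0.01 and 0.02. The covariance was 0.448 against a simulated 0.0164. With 1 h the shared genes were 323 higher and 271 lower at 6 h (72.6 and 88.5 for independent lists; covariance 0.203 against 0.0163) and 304 and 254 at 24 h (81.0 and 80.7; 0.190 against 0.0164). Controls of 3 arrays cannot be split into groups of 2, so part of this excess may come from the shared controls. Without effects, the design alone sets the simulated r and almost no gene is called, so that r and those shared counts are no yardstick here. The simulated covariance does size the part from shared controls, and it was far below the observed one for each pair of times. Errors were drawn independently for each array, so error shared by donor or slide is not in it.

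Of the remaining cell type markers, which were listed to check which other cells the cultures held, no list passed at any time. Eosinophil markers had medians of 0.15, -0.52 and -0.98 at 1, 6 and 24 h (adjusted p = 0.90, 0.598 and 0.253), with 2 of 4 lower at 24 h, Ear1 (-2.10) and Ear6 (-1.65). Mast cell and basophil markers had medians of -0.26, -0.33 and -0.25 (adjusted p = 0.228, 0.598 and 0.681). Of these 8 genes the histidine decarboxylase gene Hdc rose at all times (1.33, 4.63 and 4.81), which put the list mean above 0 at 6 and 24 h (0.21 and 0.32), while Cma1 (-0.92), Cpa3 (-0.66) and Kit were lower at 6 h. B cell markers had medians of -0.23, 0.02 and 0.14 (adjusted p = 0.228, 0.981 and 0.973), with 1 of 6 higher, Blnk (1.37 at 6 h, 0.86 at 24 h), and 1 lower, Fcrla (-1.20 and -1.32). T cell markers had medians of -0.03, -0.08 and 0.10 (adjusted p = 0.877, 0.981 and 0.969), with Lck higher (1.80 at 6 h, 1.38 at 24 h) and Thy1 lower (-1.22 and -1.27). B and T cells had been depleted from the marrow per the labels. Plasmacytoid dendritic cell markers had medians of -0.03, 0.33 and -0.18 (adjusted p = 0.877, 0.598 and 0.681), with Bst2, which interferon also induces, at 2.44 at 6 h and 2.87 at 24 h, and Pacsin1 at -0.99, -1.13 and -1.90. Erythroid markers had medians of 0.06, 0.13 and 0.25 (adjusted p = 0.877, 0.598 and 0.253), with 1 of 6 higher at 24 h, Car2 (0.83). Megakaryocyte or platelet markers had medians of 0.17, 0.06 and -0.08 (adjusted p = 0.228, 0.981 and 0.973), with Pf4 at 1.62 at 24 h and Vwf at 1.16 at 1 h and -1.26 at 24 h. Stromal markers had medians of 0.27, 0.16 and 0.39 (adjusted p = 0.228, 0.560 and 0.252), with Pdgfrb at 1.22 at 6 h and Col5a1 at 1.16 at 24 h.

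Progenitor markers had adjusted p = 0.598 at 6 h and 0.942 at 24 h. The dendritic cell and macrophage lists had medians of 0.21 and 0.13 at 6 h (0.560 each), where Irf8 (1.56), Id2 (1.48), Cd14 and Ms4a7 (1.09) rose. At 24 h 5 of 12 dendritic cell markers rose, such as Irf8 (1.58), and 3 fell, Clec10a, Dpp4 (-1.23) and Kmo (-1.06), with a median of 0.32 (0.36 with the block; adjusted p = 0.333). Only 2 natural killer cell markers were measured, too few for a test, with Klrd1 at -1.12, -1.57 and, at 24 h, lower (adjusted p = 3.8e-05) and not well above background on any array. With slide as a block no list from the eosinophil markers onward passed at the times given. Medians near 0 changed sign there for plasmacytoid (0.15 at 1 h, 0.08 at 24 h), megakaryocyte (-0.05 at 1 h, -0.24 at 6 h), B cell (-0.03 at 6 h), T cell (-0.02 at 24 h) and progenitor markers (0.05 at 24 h).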

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

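The tests of slides on whole gene counts and the counts over other splits of the arrays were planned, while the tests on cell cycle and neutrophil genes were chosen only after those results were seen.

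The first pattern is that slides and times overlap, so that slide differences could enter the counts of changed genes. If slides were the whole cause, genes called between slides would not change the same way within slides on other arrays. They did so in 99.6% of cases at 1 h, 99.5% at 6 h, 98.6% at 24 h, 95.3% for 6 h against 1 h and 96.1% for 24 h against 6 h. At 6 h and in both comparisons between times the calls between slides rest on 1 array of the later time, with the spread taken from the other arrays, so those shares alone exclude nothing. At 1 h and 24 h the calls rest on 2 arrays of each group, but the change within slides rests on single arrays. The shares at these times therefore argue only weakly against slides as the whole cause. Fitted with a slide block, 225, 1949 and 1762 genes passed at 1, 6 and 24 h. The log2 changes of the called genes stayed at a median of 0.94, 1.07 and 1.08 times (1.05 and 0.91 between times, where 2341 and 825 genes kept their call). These ratios cover genes called from the same arrays, which favours values near 1, so they are no separate evidence on slides. The block leaves fewer arrays and residual degrees of freedom. A share of slide differences in single genes was not tested.

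The second pattern is the lower level of cell cycle genes as early as 1 h (median log2 change -0.88; adjusted p = 0.232 with an estimated correlation, so the list passed with the preset one alone). On the 1 h array that shared slide 1 with the unstimulated arrays the median was -0.76, below the lowest unstimulated array (-0.15, SD 0.12), but this is 1 array and excludes nothing, so a slide difference stays open. A harvest with fewer progenitor cells may also lower these genes, but their 7 markers had a median of 0.02 (SD 0.53). Averaged over arrays, the list median of these markers lay 0.80 (SE 0.38) above that of the cell cycle genes, yet on the 1 h array of donor C the medians were close (-0.21 and -0.36), and 1 marker, Cd34, fell, so this argues only weakly against fewer progenitors as the whole cause. Other dividing cells in the harvest and regulation within the dendritic cells stay open, and neither was tested. LPS is the difference that the design names, but no unstimulated cells were kept for 1 h, so time in culture and handling go with it.

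The third pattern is the fall of neutrophil markers at 1 h, with S100a8 at -1.99, -3.30 and -2.22 for donors A, B and C. The list missed the threshold with an estimated correlation (adjusted p = 0.150). On slide 1 the median of the markers was -0.30 against a lowest unstimulated value of -0.12 (SD 0.20), which is again 1 array and leaves a slide difference open. Fewer neutrophil lineage cells in the harvest, which was not sorted, might lower all their markers; 9 of 12 were below 0 at 1 h and 4 were called lower, with changes of up to 0.63, and this cannot be told apart from lower expression within the cells. In the ratios S100a8 fell by 1.64 more than S100a9, without overlap between arrays, and in the sample channel S100a8 also fell more for donor A (12.4 to 9.75, against 15.8 to 14.2) and donor B (11.8 to 8.39, against 15.2 to 12.9) but not for donor C (11.1 to 9.53, against 15.1 to 13.2), which leaves it open. At 6 h and 24 h Lcn2 was higher (1.91 and 3.05), as was Csf3r, while 8 and 9 other markers were lower.

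For each pair of groups, the 10 splits of the 6 arrays are too few for a share under 0.05. The other splits also mix both groups unequally, which keeps part of the real difference and widens the spread, so their counts are no measure of chance. The real counts and the highest of the other splits were 827 and 0 at 1 h, 4397 and 0 at 6 h, 4372 and 0 at 24 h, 3128 and 24 for 6 h against 1 h, and 2042 and 6 for 24 h against 6 h. For genes changed by at least 2-fold they were 278, 1314, 1332, 831 and 425 against 0, 0, 0, 19 and 4, and in each case 1 split, the real one, reached the count. For list shifts, 19, 13 and 12 lists passed in the real split and up to 13, 15 and 14 in another, with 1, 5 and 7 of the 10 splits reaching the real number. Among the 4 splits that part all 3 donor pairs, the real one included, the others gave 0 genes in every comparison and up to 13, 14 and 14 lists. For the time course, 1 of 100 splits, the real one with 5739 genes, reached the count, and the highest other gave 752. This argues against a random assignment of arrays to groups, though 100 splits can give no share under 1 in 100. The splits were drawn without regard to slide or donor, so they say nothing on slides, which overlap with times.

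Several named genes were called in opposite directions at different times, and the difference between the times, which follows from the 2 calls and adds no evidence of its own, is given beside them. From 1 h to 6 h the direct difference was -3.73 for Errfi1 (2.89 to -0.85), -1.38 for Jun (0.81 to -0.57), -1.52 for Rgs2 (0.67 to -0.84) and -1.75 for Treml1 (1.00 to -0.75). From 6 h to 24 h it was 2.18 for Gadd45g (-1.46 to 0.72), -1.46 for Mertk (0.78 to -0.68), 1.44 for Tgm2 (-0.97 to 0.48) and -1.74 for Tnip3 (0.88 to -0.86). From 1 h to 24 h it was -4.14 for Mrc1 (1.22 to -2.92), 4.26 for Plac8 (-1.53 to 2.73), -3.54 for Tnip3 (2.67 to -0.86), 2.34 for Gadd45g, -2.42 for Vwf (1.16 to -1.26), -2.38 for Rgs2 (0.67 to -1.71), -2.15 for Bcl2l11 (1.35 to -0.81), -2.01 for Egr2 (1.15 to -0.87), -1.72 for Treml1, -1.63 for Jun (0.81 to -0.82) and -0.96 for Icosl (0.56 to -0.40). Not every one of these calls held with slide as a block: those of Fos and Jun at 6 h, of Plac8, Mrc1 and Vwf at 1 h, of Treml1 at each time, and of Vwf, Bcl2l11, Egr2, Jun, Tnip3 and Icosl at 24 h were among those lost. For Fos the fit gave -1.92 from 1 h to 6 h, but its probe was not well above background on any 6 h array and its direction against unstimulated cells turned within slides, so neither a size nor a reversal is claimed. Groups of 3 arrays are too small to test single arrays as outliers.

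Probes without a gene symbol, which no comparison of genes used, carried signal as well. Of 6646 such probes past the filter, 605 were called at 1 h (283 higher, 322 lower), 1898 at 6 h (916 and 982) and 1852 at 24 h (794 and 1058).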

How the results depend on the processing

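Fits without slide 2, with normexp on all spots, with all marked spots left out and with slide as a random block were chosen after seeing the data; unless stated otherwise, the cause of a shift was not tested. Mean signals, which the plan named, were not run because the files used here hold none, the median signals that it named as an alternative became the signals used, and Aquantile leaves the ratios as they are by construction. Counts in order are 1 h, 6 h, 24 h, 6 h against 1 h, 24 h against 6 h and the time course. With donor as a block (replicate pairing) they were 1129, 4695, 4742, 3464, 2408 and 6205, and with slide as a random block 675, 3793, 3753, 3285, 1842 and 5271, all within 1.5 times of those reported. The donor block changed the calls of 4 lists and of Nos2, Tlr4, H2-D1, Ciita and Ifnb1 given beside them in the report, and no other call of a list or named gene. Median centring gave 225, 2024, 2335, 1449, 928 and 2797. Slide as a fixed block gave 225 (175 by at least 2-fold) at 1 h, 1949, 1762, 868 for 24 h against 6 h and 3145 over the time course, with fewer degrees of freedom by construction. Normexp on all spots gave 243 (161 by at least 2-fold), 2435, 1377 for 6 h against 1 h, 798 (271) for 24 h against 6 h and 3424 over the time course; 1 array failed there. Every probe as its own feature gave 1737 (514), 7511 (2128), 7512 (2063), 5385 (1354), 3366 (666) and 10179, over more features by construction. Processed scanner signals gave 2068, 2042, 1313 and 740 genes of at least 2-fold for the later 4 comparisons. Only the groups compared gave 1355 for 24 h against 6 h, and without slide 2 474 genes passed at 1 h, both with fewer arrays. The other settings kept every count within 1.5 times.

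Leaving out 1 array at a time gave 338 to 1046 genes at 1 h (199 to 416 by at least 2-fold), 3375 to 4634 at 6 h (1207 to 1576), 3472 to 4652 at 24 h (1230 to 1523), 2083 to 3185 for 6 h against 1 h (767 to 1024), 1080 to 2309 for 24 h against 6 h (355 to 521), 4843 to 5846 over the time course and 41 to 49 list shifts in place of 44. At 1 h the count moved over 1.5 times without unstimulated A (338) or B (356) and without 1 h A (528) or B (399); for 6 h against 1 h without 6 h A (2083); and for 24 h against 6 h without 6 h A (1080), 6 h B (1290) or 24 h C (1270).

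With all marked spots left out, 12 lists that had passed lost their call and 1 turned, over fewer genes by construction. With normexp on all spots 6 lost it. Under 1 of 29 settings, all marked spots left out, this held for feedback inhibitors at 1 h (adjusted p = 0.203), immediate early genes at 24 h (0.075), lysosomal genes at 6 h (0.061), MHC class I at 24 h (0.144) and apoptosis regulators at 24 h (0.060). Dendritic cell maturation lost its call at 1 h and 6 h (0.059 and 0.064) with normexp on all spots. IL-4 responsive genes at 1 h lost it under both settings (up to 0.077). Respiration at 6 h and neutrophil markers at 1 h lost it under 3 settings (up to 0.092 and 0.136), cholesterol synthesis, cytoskeleton and respiration at 1 h under 6 (up to 0.480, 0.091 and 0.409), macrophage markers at 1 h under 8 (up to 0.429) and conventional dendritic cell markers at 1 h under 12 (up to 0.201). Some lists passed in other settings only. The ribosomal list at 24 h missed the threshold in 24 of 29, with medians from -0.51 to 0.08 and adjusted p down to 6.9e-06, and passed without slide 2 (0.00019). The MHC class II and interferon lists at 1 h missed it in 21 each, the nitric oxide and prostaglandin list at 24 h in 20, the ribosomal list at 6 h in 19, lipid handling at 24 h in 17 and lysosomal genes at 24 h in 16.

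Some directions turned, beside the list medians near 0 that the report gives as turned with median centring, the slide block or within slides. The interferon list median at 1 h was -0.084 with median centring and -0.074 with the Cy5 channel alone, the nitric oxide and prostaglandin list at 6 h -0.022 with processed signals, and the immediate early list at 6 h -0.032 with all marked spots left out, where its call was lost (adjusted p = 0.369). With processed signals Tnfsf4 and Marchf1 at 1 h were at -0.046 and -0.60 and H2-Aa at 6 h at -0.46; with the mean of probes Dnajb1 at 24 h was at 0.00127; with normexp on all spots at 6 h Fos, not well above background there, was at 0.36, Ccr7 -0.13, H2-Oa -0.15, H2-Aa -0.62, Fabp4 -0.13, Pdcd1lg2 -0.32 and Cish -0.054. Dim probes limit what the arrays resolve, since 48.1 to 57.6% of probes were well above background in the sample channel.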

Other observations

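The tallies of opposite directions, donors and single genes in this part were chosen only after the results were seen.

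Across all genes, changes of opposite direction between times were few. There were 24 genes called higher at 1 h and lower at 24 h, among them the uptake receptor Mrc1 and the death regulator Bcl2l11, and 13 called lower at 1 h and higher at 24 h, among them Plac8 and Gadd45g. Between 1 h and 6 h the counts were 13 and 14, and between 6 h and 24 h 29 and 27. Some members of the same fixed list moved apart, given as single genes without a test of such pairs: at 24 h the inducible cyclooxygenase Ptgs2 was at least 21.2-fold higher while the constitutive Ptgs1 was at -1.97, and among scavenger receptors Marco stood at 5.26 while Mrc1 stood at -2.92. The inducible chaperone Hspa1a was at 3.63 at 6 h and 5.10 at 24 h (SE 0.85), while the mitochondrial chaperones Hspd1 and Hspe1 were at -1.18 and -0.61 at 6 h and at -1.08 and -0.44 at 24 h. Cytokines near the limit of detection in unstimulated cells included Il23a and Il12a, called higher at all 3 times, the latter by at least 1.81-fold at 1 h.

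The size of the response differed between donors, as values without a test. The slope of a donor's changes on those of the other donors, over the called genes, was 0.932, 1.26 and 0.751 for donors A, B and C at 1 h, 1.08, 1.15 and 0.725 at 6 h, and 0.773, 1.15 and 0.991 at 24 h. Cell cycle genes had per-array medians of -0.76, -1.42 and -0.36 at 1 h, -1.73, -2.00 and -0.91 at 6 h and -1.66, -2.08 and -2.07 at 24 h, in the same order. Both are confounded with slide, since the arrays of donor B at 1 h and 24 h made up slide 2.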
